A study of Homo sapiens with 6 samples.

How the data were processed

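The series holds 6 RNA-seq libraries from LATS1/2-inactivated RPE1 cells, 3 transfected with control siRNA and 3 with siRNA against MK5. Per the labels' protocols, cells were transfected with a lipid reagent and libraries were made from total RNA with the TruSeq V2 RNA kit. The submitters' processing notes name FastQC, Trimmomatic 0.36, TopHat2 2.1.1, HTSeq 0.9.1 and the genome build GRCh37, without the order or settings. The annotation release, the strand setting of the counting and the siRNA sequences are not given in the sources used here. Without strand, reads of genes that overlap on opposite strands cannot be told apart.

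The deposited table holds 36884 genes with an identifier and a symbol, and 1 column of counts per library. Although the table's name speaks of CPM, the deposited values are whole-number counts, since they sum to between 27188074 and 28236773 per library and low values of replicates 2 and 3 vary as sampled reads do. The variance over the Poisson value was 0.995 in the controls and 1.02 in the MK5 siRNA libraries for genes with mean counts from 2 to 5. It was 2.87 and 1.95 for means from 200 to 1000, and 12.2 and 7.56 for means of at least 1000. Replicates 2 and 3 of a group thus differed by more than sampling noise and were kept as separate libraries. A repeat of library preparation from the same culture would also exceed sampling noise, so the counts do not show whether replicates 2 and 3 are separate cultures. If they are not, each group holds fewer than 3 independent replicates. No row stood for unassigned reads. A total of 14359 genes had no count in any library, and 1859 symbols were repeated. A repeated symbol in a list was represented by its row of highest mean. CPM values came from edgeR's cpm function with TMM-scaled library totals. Symbols of 9 tested genes were bare numbers, as spreadsheets make of some names, and these genes were kept under their identifiers. Genes of the lists that are missing from the table were not analysed here. The reference sequences at hand were GRCh38, which differs from the build named by the submitters, so no coordinates are given. They were used for transcript lengths, base composition and sequence words, matched by gene identifier.

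The main test was planned for CPM values with limma, with edgeR to be used if the values were counts, so edgeR was used. In R 4.3.3, edgeR 4.0.16 kept genes with filterByExpr (least count 10, least total count 15), which left 13431 genes. Libraries were scaled by TMM, and the quasi-likelihood test compared MK5 siRNA with control siRNA without a block. Adjusted p is Benjamini-Hochberg over the genes tested, two-sided, with a threshold of 0.05. The standard error of a log2 fold change is its size divided by the square root of the F value. The common biological coefficient of variation was 21.2% over all libraries and 4.63% in replicates 2 and 3 alone. Changes within a replicate pair are differences of log2(CPM + 0.5).

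A total of 34 gene lists were fixed from textbook knowledge before the data were examined, as were the main test, the alternatives other than those named below as added and the rule for named genes. Lists with at least 5 measured members (33 lists) were tested with camera (limma 3.58.1), with a preset correlation of 0.01 between members and Benjamini-Hochberg adjustment over the lists. Camera with an estimated correlation and fry were alternatives. With an estimated correlation, camera refers its statistic to the residual degrees of freedom of the 6 libraries, which leaves it little power. The counts of members adjusted over the list alone use Benjamini-Hochberg within the list. The named genes are MAPKAPK5, CYR61, CTGF, ANKRD1, AMOTL2, AXL, YAP1, WWTR1, LATS1 and LATS2. To these are added the 10 largest rises and 10 largest falls among passing genes with a mean of at least 5 CPM and groups apart, and the passing members with the largest changes in each list, up to 4 in a list that passed camera and up to 2 in another.

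The groups share replicate numbers 1 to 3. Deviations from the group means, across genes, correlated at 0.284, 0.211 and 0.244 between libraries of the same number. By the rule set for this check the numbers were taken to pair the libraries. This pairing was read from the data, since the labels name no shared day or batch. Replicates 2 and 3 also correlated with each other across groups (0.171 and 0.188), and replicate 1 ran against both, at −0.219 to −0.275. Deviations within a group sum to 0, so a replicate 1 that stands apart turns replicates 2 and 3 the other way. The values therefore show a deviation partly shared by replicate 1 of both groups. They hardly tell a pairing of replicates 2 and 3 by number from the crossed one. The first principal component (71.0% of the variance) parted the groups, and the second (21.2%) parted control replicate 1 from the rest. Values within replicate pair 1 and within pairs 2 and 3 are therefore given for MAPKAPK5, YAP1 and ITGB2, for the lists that passed, and for lists whose median differed in sign or lay more than 2 times as far from 0 in pair 1. A fit with the replicate number as a block was an alternative.

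Libraries differed in total by at most 1.04-fold. A count of 3 corresponds to 0.110 CPM in the smallest library, which is the floor for a gene with no count, and such limits cover counting error only. On simulated counts drawn from these libraries' means and spread, for MK5 siRNA against control siRNA over 13431 genes, edgeR recovered 0% of 67 genes changed 1.5-fold, 43.3% of 67 changed 2-fold and 84.8% of 66 changed 4-fold, and called 1 unchanged gene. With few changed genes the adjusted threshold is stricter than in the real comparison, so these shares do not carry over to it. Camera found the list that was moved and called 1 other list.

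Alternatives were limma on log2(CPM + pseudocount) with 0.5, 0.1 and 2, quantile normalization with limma, DESeq2 1.42.0, median-ratio scaling, scaling by library totals alone, no filter, a mean of at least 1 or 5 CPM, no abundance trend, a robust fit, the replicate block, each library left out in turn, replicate 1 left out in both groups, and genes with a sequence word left out. Those added after the data were seen were limma with 0.5, scaling by totals, the mean of at least 1 CPM, leaving out replicate 1 in both groups and leaving out genes with a word. All words of 7 bases held by at least 30 genes were scored in 3′ UTRs of at least 50 bases for their association with the log2 fold change. The scores were corrected for 3′ UTR length, base composition and the gene's mean level, and set against 100 shuffles of the genes. In 5 of 5 simulated runs over 12299 genes, a word planted with an effect of −0.2 on the log2 scale ranked first. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 was used for the word counts and figures.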

Results

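RNA was sequenced from RPE1 cells, an immortalized, non-transformed line of human retinal pigment epithelium, in which both LATS1 and LATS2 had been inactivated with CRISPR-Cas9. LATS1 and LATS2 are the kinases of the Hippo pathway that phosphorylate and restrain the transcriptional coactivators YAP and TAZ. The cells were transfected with control siRNA or with siRNA against MK5, a protein kinase encoded by MAPKAPK5, and collected 48 h later. Each group held 3 libraries, described by the submitters as biological replicates. The control libraries held 28236773, 27594088 and 27698952 counts in replicates 1, 2 and 3, and the MK5 siRNA libraries held 27485598, 27188074 and 28188824. The comparison asks how transcription, and that of YAP target genes in particular, changes when MK5 is lowered in cells without LATS kinases. Fold changes below are MK5 siRNA over control siRNA on the log2 scale, with the standard error of edgeR's quasi-likelihood fit (n = 3 per group). Levels are counts scaled to a common library size by TMM (CPM), as mean ± SD over 3 libraries.

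MAPKAPK5 (ENSG00000089022), the siRNA's target, was lower in every MK5 siRNA library than in every control library. Its level was 35.6, 29.05 and 31.3 CPM in control replicates 1, 2 and 3, and 17.4, 14.1 and 16.2 CPM in MK5 siRNA replicates 1, 2 and 3. The mean fell from 32.0 ± 3.30 to 15.9 ± 1.66 CPM, a log2 fold change of −1.01 ± 0.14 (edgeR adjusted p = 0.00169). The fall was −1.01, −1.02 and −0.93 in replicate pairs 1, 2 and 3, on CPM with 0.5 added. LATS1 (ENSG00000131023) and LATS2 (ENSG00000150457) were still counted, at 16.6 ± 3.10 and 37.5 ± 5.27 CPM in the control libraries, which says nothing on the edits, since a gene can be inactivated without losing its transcript. Their log2 fold changes of 0.14 ± 0.19 and 0.10 ± 0.18 did not pass (edgeR adjusted p = 0.583 and 0.689), and neither kept its direction when single libraries were left out. LATS1 gave −0.01 without MK5 siRNA replicate 1, and LATS2 gave −0.02 without control replicate 3 and −0.09 without MK5 siRNA replicate 1.

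MK5 siRNA changed a large part of the transcriptome. Of 13431 genes tested, 3020 rose and 3186 fell (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p below 0.05), which is 46.2% of those tested. A total of 1447 rose and 1543 fell by at least 2-fold, and 364 rose and 366 fell by at least 4-fold. The largest rises among genes of at least 5 CPM, with all libraries of the groups apart, were in NR4A3 (6.62 ± 0.55), an orphan nuclear receptor induced by many stimuli, CADM1 (5.58 ± 0.29), a cell adhesion molecule, and FOSB (4.97 ± 0.54) and FOS (4.71 ± 1.05), subunits of the AP-1 transcription factor. HES1 (4.47 ± 0.32), a repressor induced by Notch, CYP1A1 (4.14 ± 0.32), the cytochrome induced by the aryl hydrocarbon receptor, and SNAI1 (3.77 ± 0.30), a repressor of epithelial genes, followed, with GPRC5C (4.33 ± 0.47), KCP (4.17 ± 0.55) and the noncoding RNA LINC02154 (3.81 ± 0.25). The largest falls were in NPPB (−6.46 ± 1.53), the natriuretic peptide B gene, and ITGB2 (−6.08 ± 1.18), the leukocyte integrin beta chain, which kept 16 and 13 counts in all 3 MK5 siRNA libraries together. ABCA13 (−5.05 ± 0.61), GPRC5B (−4.15 ± 0.66), DIRC3 (−4.13 ± 0.62), PDGFB (−4.05 ± 0.90), a growth factor, KRT81 (−3.81 ± 0.30), a hair keratin with near-identical relatives, ANKRD1 (−3.79 ± 0.41), AOX1 (−3.70 ± 0.42), aldehyde oxidase, and CAVIN2 (−3.68 ± 0.23), a component of caveolae, completed the falls. For these 20 genes edgeR's adjusted p lay between 0.000178 in CADM1 and 0.0129 in NPPB.

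Replicate 1 stood apart from replicates 2 and 3 in both groups, and several of these sizes rested on it. NPPB was at 44.7 CPM in control replicate 1 and at 3.24 and 2.27 CPM in replicates 2 and 3. Its log2 fold change was −3.85 without control replicate 1, and it did not pass without MK5 siRNA replicate 1 (edgeR adjusted p = 0.0612) or replicate 2 (edgeR adjusted p = 0.0530), nor in limma with a pseudocount of 2 (−2.22, limma adjusted p = 0.07004). FOS reached 29.7 CPM in MK5 siRNA replicate 1 and 3.58 and 3.27 CPM in the others, and its log2 fold change was 2.88 without MK5 siRNA replicate 1. ITGB2 was at 0.881 CPM in control replicate 1 against 17.2 and 13.5 CPM in replicates 2 and 3, so that it changed by −1.27, −4.64 and −4.39 in replicate pairs 1, 2 and 3, on CPM with 0.5 added, which shrinks changes at low levels. Its fitted log2 fold change was −6.31 without replicate 1 in both groups, so its size over all libraries did not rest on replicate 1. All libraries of the groups were apart in 60.4% of all tested genes, where chance gives 10% for independent libraries. If replicates 2 and 3 are not separate cultures, chance gives a higher share. With replicates 2 and 3 alone, 10372 of 13690 genes changed.

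**Figure D1:**
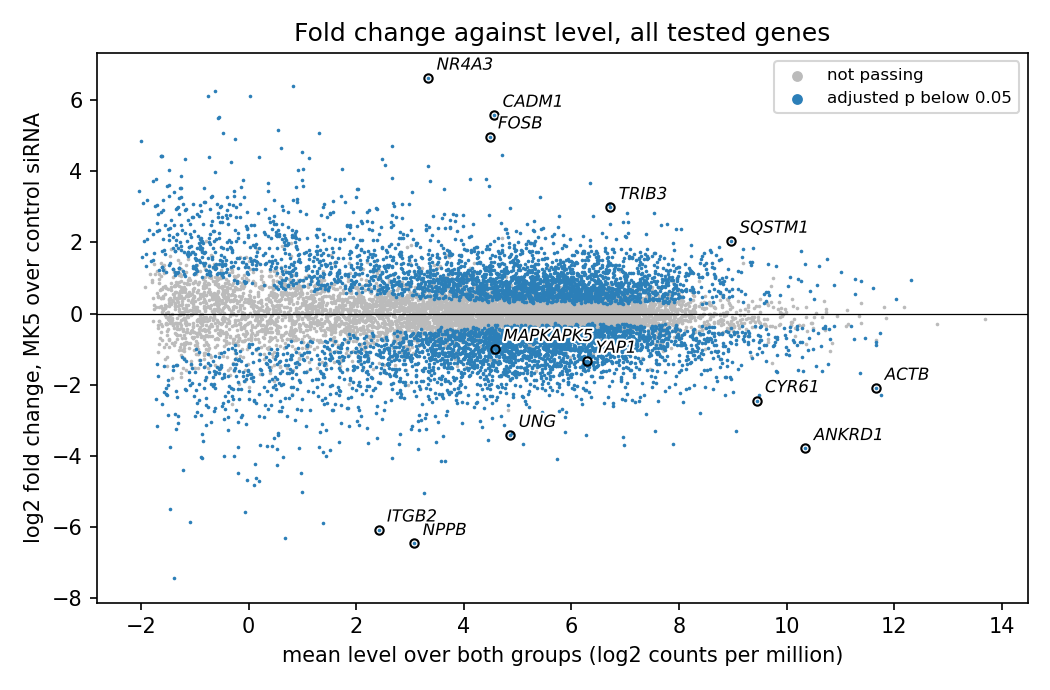
Log2 fold change of MK5 over control siRNA against the mean level of both groups in log2 CPM, 1 point per tested gene. Blue points are the 6206 genes that passed edgeR's test, with named genes circled, such as NR4A3 at 6.62 and NPPB at −6.46.

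YAP1 and most of the listed YAP and TAZ target genes were lower after MK5 siRNA. YAP1 (ENSG00000137693) fell from 112 ± 27.8 to 44.5 ± 0.988 CPM, a log2 fold change of −1.34 ± 0.18 (edgeR adjusted p = 0.00151), with −1.70, −1.15 and −1.05 in replicate pairs 1, 2 and 3, on CPM with 0.5 added. WWTR1 (ENSG00000018408), which encodes TAZ, fell from 110.2 ± 3.85 to 77.2 ± 5.41 CPM, by −0.51 ± 0.10 (edgeR adjusted p = 0.00615). Of 21 YAP and TAZ target genes, 15 fell, none rose and 6 did not pass, and 15 also fell when adjusted over the list alone. ANKRD1 (ENSG00000148677), a cardiac and muscle ankyrin repeat protein, fell from 2433 ± 1392 to 176 ± 19.0 CPM, by 13.8-fold (−3.79 ± 0.41, edgeR adjusted p = 0.000714). The matricellular protein gene CYR61 (ENSG00000142871) fell from 1174 ± 239 to 216 ± 130.2 CPM (−2.44 ± 0.41, edgeR adjusted p = 0.00358), and AMOTL2 (ENSG00000114019), an angiomotin that binds YAP, fell from 454 ± 25.3 to 104 ± 5.45 CPM (−2.13 ± 0.10, edgeR adjusted p = 0.000148). FJX1 (−2.39 ± 0.12) and CRIM1 (−2.30 ± 0.20) were the other members with the largest falls. CTGF (ENSG00000118523) fell by −2.20 ± 0.62 (edgeR adjusted p = 0.0245), from 842 ± 737 to 183 ± 74.3 CPM. Its log2 fold change was −1.18 without control replicate 1, and it did not pass without MK5 siRNA replicate 2 (edgeR adjusted p = 0.0872) or replicate 3 (edgeR adjusted p = 0.0864). AXL (ENSG00000167601), a receptor tyrosine kinase, fell by −0.74 ± 0.20 (edgeR adjusted p = 0.0201), by −0.49 without control replicate 1, and did not pass without MK5 siRNA replicate 2 (edgeR adjusted p = 0.0796) or replicate 3 (edgeR adjusted p = 0.0771). The list's median log2 fold change was −1.40 (camera adjusted p = 6.39e-08; adjusted p = 0.252 with an estimated correlation).

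**Figure D2:**
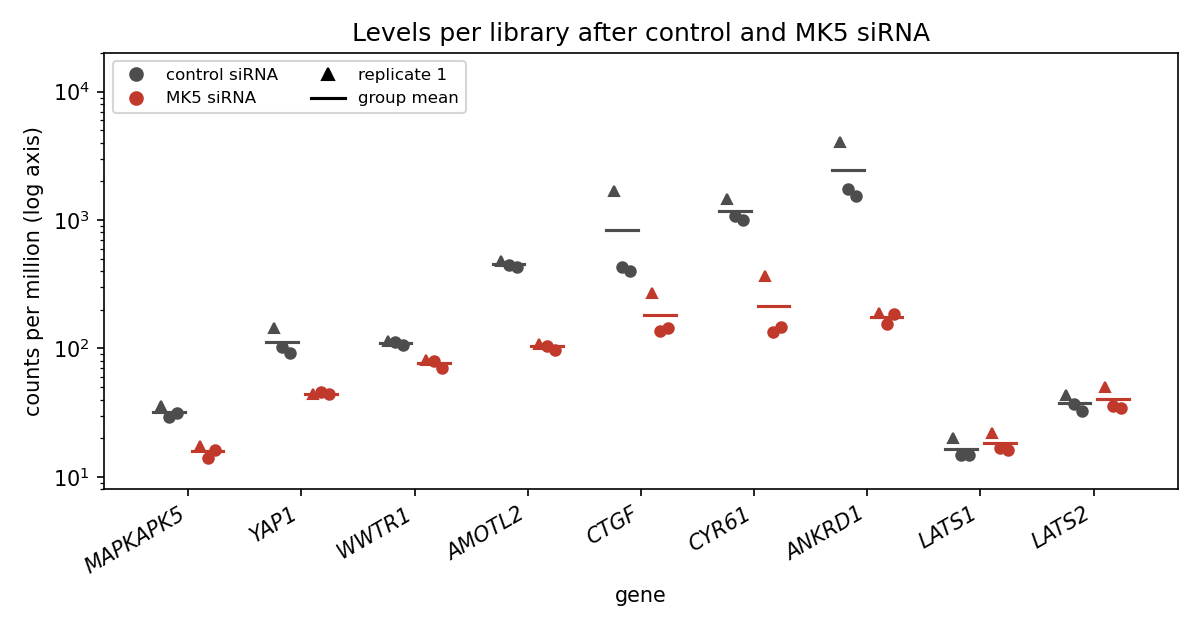
CPM on a log axis in each library for MAPKAPK5, YAP1, WWTR1, 4 YAP target genes, LATS1 and LATS2, with control siRNA in grey, MK5 siRNA in red, replicate 1 as a triangle and the group mean as a bar. All control points lie above all MK5 siRNA points for MAPKAPK5, YAP1, WWTR1, AMOTL2, CTGF, CYR61 and ANKRD1, and the groups overlap for LATS1 and LATS2.

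The list of Hippo pathway components also passed downward. Among 30 components, 11 fell and 3 rose, and the same numbers fell and rose when adjusted over the list alone. The scaffold AMOT fell by −2.24 ± 0.48, the atypical cadherin FAT1 by −1.58 ± 0.16 and FRMD6, an upstream FERM protein, by −1.56 ± 0.10, while VGLL4, a competitor of YAP for TEAD proteins, rose by 1.35 ± 0.25 (edgeR adjusted p from 0.000209 to 0.00891). The median was −0.31 (camera adjusted p = 0.0139; adjusted p = 0.656 with an estimated correlation). The list did not pass without control replicate 1, with a median of −0.19 (camera adjusted p = 0.0505), nor without genes that hold the sequence word TCCAGTT or CCAGTTA in the 3′ UTR, with −0.20 (camera adjusted p = 0.122). The latter left out 11 of the 30 components (36.7%, against 22.2% of all genes scored). An effect of the sites therefore cannot be told apart from that of a shorter list.

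The list of actin cytoskeleton genes passed downward. Of 23 SRF and actin cytoskeleton genes, 15 fell and none rose, with 17 falling when adjusted over the list alone. The cytoplasmic actins ACTG1 and ACTB fell from 5753 ± 427 to 1172 ± 371 CPM (−2.29 ± 0.23) and from 5272 ± 1105 to 1233 ± 176 CPM (−2.10 ± 0.20). The actin-binding calponins CNN1 and CNN3 fell by −4.48 ± 0.63 and −1.89 ± 0.26 (edgeR adjusted p from 0.000456 to 0.00182 over the 4 genes). The list's median was −0.96 (camera adjusted p = 3.13e-06; adjusted p = 0.454 with an estimated correlation). Both actins have pseudogenes and a close relative in each other, so reads could be split between copies. Of 24 integrins and focal adhesion genes, 10 fell and 3 rose, and 10 and 4 did when adjusted over the list alone. PTK2, the focal adhesion kinase, fell from 216 ± 8.85 to 44.9 ± 2.62 CPM (−2.27 ± 0.10) and the caveolar protein gene CAV1 by −1.55 ± 0.11 (edgeR adjusted p = 0.000148 and 0.000211). This list's median was −0.14 and it did not pass with all 6 libraries (camera adjusted p = 0.0768). It passed without replicate 1 in both groups, with a median of −0.10 (camera adjusted p = 0.0275).

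Cell cycle genes fell almost throughout. Of 43 G1 and S phase genes, 41 fell, none rose and 2 did not pass, and 42 fell when adjusted over the list alone. The largest falls were in UNG, the uracil DNA glycosylase (−3.42 ± 0.16, from 53.2 ± 7.96 to 4.97 ± 0.365 CPM), CDCA7 (−3.07 ± 0.25), TYMS, thymidylate synthase (−2.92 ± 0.26, from 105 ± 16.7 to 13.8 ± 4.06 CPM), and the helicase gene BLM (−2.89 ± 0.32), with edgeR adjusted p from 0.000148 to 0.000791. The list's median was −1.78 (camera adjusted p = 4.44e-23; adjusted p = 0.252 with an estimated correlation). Of 54 G2 and M phase genes, 47 fell and none rose, and 50 fell when adjusted over the list alone. CDC20, an activator of the anaphase-promoting complex, fell from 246 ± 151 to 44.0 ± 6.39 CPM (−2.49 ± 0.41), the spindle protein gene PSRC1 by −2.26 ± 0.25, CDCA8, a chromosomal passenger, by −2.25 ± 0.31 and ANLN, anillin, by −2.24 ± 0.35 (edgeR adjusted p from 0.000789 to 0.00333). The median was −1.30 (camera adjusted p = 1.41e-12; adjusted p = 0.654 with an estimated correlation). Of 9 replication-dependent histone genes measured, none rose and HIST2H2AC, a member of a multicopy family at 0.559 CPM in controls, fell by −1.86 ± 0.40 (edgeR adjusted p = 0.00945), as it did when adjusted over the list alone. The median of that list was 0.71 and it did not pass (camera adjusted p = 0.634). Only 9 of its 25 members were measured, at a summed 57.0 CPM in controls, and control replicate 1 lay at −1.78 against the other controls. The list therefore cannot show whether histone transcripts followed the cell cycle genes.

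The list of immediate early genes passed upward. Of 19, 10 rose and 1 fell, and 13 rose and 1 fell when adjusted over the list alone. Beside FOSB and FOS, the nuclear receptor gene NR4A2 rose from 2.37 ± 0.659 to 32.4 ± 16.8 CPM (3.77 ± 0.42, edgeR adjusted p = 0.000803), and EGR2 rose by 2.81 ± 0.79 at under 1 CPM in both groups (edgeR adjusted p = 0.0242). EGR2 did not pass without control replicate 3 (edgeR adjusted p = 0.0706) or MK5 siRNA replicate 1 (edgeR adjusted p = 0.0693), nor in limma with a pseudocount of 2 (0.43, limma adjusted p = 0.0614) or after quantile normalization (0.94, limma adjusted p = 0.0723). The list's median was 1.60 (camera adjusted p = 0.00819; adjusted p = 0.798 with an estimated correlation), and 0.75 without MK5 siRNA replicate 1. The list did not pass without control replicate 1 (camera adjusted p = 0.0665). Among 17 ERK feedback genes, 3 rose and 5 fell, with 4 and 5 when adjusted over the list alone. CCND1, cyclin D1, fell from 1615 ± 858 to 414 ± 20.6 CPM (−1.97 ± 0.34) and IER3 rose by 1.82 ± 0.23 (edgeR adjusted p = 0.00410 and 0.00129). Their list did not pass (camera adjusted p = 0.797), with a median of −0.05, a mean of 0.07 and an upward direction in camera. Of 17 measured genes of the p38 and MK kinase module, 3 rose and 1 fell, both over all genes and adjusted over the list alone. HSPB1, the small heat shock protein that MK kinases phosphorylate, fell by −1.13 ± 0.21 (edgeR adjusted p = 0.00536). ZFP36, which encodes an mRNA-destabilizing protein, rose by 1.00 ± 0.25 (edgeR adjusted p = 0.0152) but did not pass without control replicate 2 (edgeR adjusted p = 0.0507) or replicate 3 (edgeR adjusted p = 0.0541). This list did not pass either (camera adjusted p = 0.918), with a median of −0.08, a mean of −0.12 and an upward direction in camera.

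The lists of the endoplasmic reticulum and amino acid stress responses passed upward. Of 20 unfolded protein response genes, 16 rose and 1 fell, and 17 rose and 1 fell when adjusted over the list alone. HERPUD1, a component of the degradation machinery of the endoplasmic reticulum, rose from 47.1 ± 5.71 to 211 ± 20.5 CPM (2.16 ± 0.14), the transcription factor gene XBP1 from 43.5 ± 14.7 to 185 ± 16.9 CPM (2.09 ± 0.24), the cochaperone gene DNAJC3 by 1.72 ± 0.16 and the ubiquitin ligase gene SYVN1 by 1.58 ± 0.14 (edgeR adjusted p from 0.000209 to 0.000883). The median was 0.84 (camera adjusted p = 6.39e-08; adjusted p = 0.252 with an estimated correlation). Of 25 ATF4 target genes, 18 rose and none fell, also when adjusted over the list alone. The pseudokinase gene TRIB3 rose from 23.7 ± 2.24 to 187 ± 9.74 CPM (2.98 ± 0.12), DDIT3, which encodes CHOP, from 6.52 ± 1.27 to 51.3 ± 13.3 CPM (2.98 ± 0.25), the cystine transporter gene SLC7A11 by 2.82 ± 0.31 and ASNS, asparagine synthetase, by 2.57 ± 0.46 (edgeR adjusted p from 0.000148 to 0.00426). The list's median was 1.15 (camera adjusted p = 3.97e-10; adjusted p = 0.252 with an estimated correlation).

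The NRF2 and lysosomal lists passed upward as well. Of 22 NRF2 target genes, 10 rose and 1 fell, and 11 rose and 1 fell when adjusted over the list alone. Apart from SLC7A11, the growth inhibitor gene OSGIN1 rose by 2.16 ± 0.23, the autophagy receptor gene SQSTM1 from 196 ± 14.4 to 806 ± 40.8 CPM (2.04 ± 0.11) and HMOX1, heme oxygenase 1, by 1.89 ± 0.13 (edgeR adjusted p from 0.000178 to 0.000720). The median was 0.93 (camera adjusted p = 5.28e-05; adjusted p = 0.654 with an estimated correlation). Of 29 lysosome and autophagy genes, 15 rose and none fell, with 16 rising when adjusted over the list alone. WIPI1, which acts in autophagosome formation, rose by 2.07 ± 0.11, the sialidase gene NEU1 by 1.82 ± 0.12 and the protease gene CTSL by 1.52 ± 0.11 (edgeR adjusted p from 0.000178 to 0.000235). The median of this list was 0.59 (camera adjusted p = 1.15e-06; adjusted p = 0.14 with an estimated correlation).

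The list of interferon response genes passed downward, with members changed in both directions. Of 25 measured, 13 fell and 5 rose, the same numbers as when adjusted over the list alone. IFIT1, IFIT3 and IFIT2, interferon-induced proteins with tetratricopeptide repeats, fell by −2.99 ± 0.27, −2.06 ± 0.19 and −2.05 ± 0.39, while IFI27 rose by 3.07 ± 0.39 from 0.186 ± 0.0968 CPM (edgeR adjusted p from 0.000427 to 0.00544). The median was −1.11 (camera adjusted p = 0.0136; adjusted p = 0.613 with an estimated correlation). Of 19 NF-kB and inflammatory genes, 9 rose and 3 fell, also when adjusted over the list alone. The chemokine genes CXCL2 and CXCL3 rose by 3.56 ± 0.82 and 3.31 ± 0.54, to 1.68 ± 1.39 and 5.96 ± 4.19 CPM (edgeR adjusted p = 0.0119 and 0.00317). The list's median was 0.49 and it did not pass with all 6 libraries (camera adjusted p = 0.0804). It passed without MK5 siRNA replicate 2 (camera adjusted p = 0.0139) or replicate 3 (camera adjusted p = 0.0202).

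The lists of ribosome production passed downward, with part of their members falling. Of 27 MYC and ribosome biogenesis genes, 15 fell and 1 rose, over all genes and adjusted over the list alone. The nucleolar protein genes UTP20 and LYAR fell by −1.45 ± 0.14 and −1.35 ± 0.26, the RNA polymerase I subunit gene TWISTNB by −1.24 ± 0.17 and MRTO4 by −1.20 ± 0.13 (edgeR adjusted p from 0.000495 to 0.00578). The median was −0.36 (camera adjusted p = 0.00407; adjusted p = 0.656 with an estimated correlation). Of 53 cytosolic ribosomal proteins, 20 fell and none rose, with 14 falling when adjusted over the list alone. RPS20 fell from 833 ± 63.7 to 307 ± 16.1 CPM (−1.44 ± 0.11), RPL23 by −0.74 ± 0.11, RPLP0 by −0.69 ± 0.13 and RPL12 by −0.65 ± 0.12 (edgeR adjusted p from 0.000252 to 0.00536). Ribosomal protein genes have many processed pseudogenes that could take part of their reads. The median was −0.32 (camera adjusted p = 0.00180; adjusted p = 0.802 with an estimated correlation), and the list did not pass after quantile normalization, with a median of −0.07 (camera adjusted p = 0.0927).

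The lists of energy and sterol metabolism did not pass, although some members changed. Of 29 nuclear oxidative phosphorylation genes, 3 fell and none rose, also when adjusted over the list alone. ATP5A1 and COX4I1, subunits of ATP synthase and cytochrome oxidase, fell by −0.85 ± 0.09 and −0.62 ± 0.10 (edgeR adjusted p = 0.000718 and 0.00302), and the list's median was −0.03 (camera adjusted p = 0.634). Of 13 mitochondrially encoded genes, MT-ND1 rose by 0.46 ± 0.12 (edgeR adjusted p = 0.0170), none did when adjusted over the list alone, and the median was 0.12 (camera adjusted p = 0.634). MT-ND1 did not pass without control replicate 2 (edgeR adjusted p = 0.0544), control replicate 3 (0.0611) or MK5 siRNA replicate 3 (0.0728). Of 24 cholesterol synthesis genes, 4 fell and none rose, also when adjusted over the list alone, with a median of −0.62 (camera adjusted p = 0.0994). This list passed with the replicate number as a block (camera adjusted p = 0.0260) and without control replicate 2 (0.0283), control replicate 3 (0.0121) or MK5 siRNA replicate 1 (0.0478). It also passed on limma's values with a pseudocount of 0.5 (camera adjusted p = 0.0406), 0.1 (0.0424) or 2 (0.0437). Its median was −0.895 in replicate pair 1 and −0.28 in pairs 2 and 3, on CPM with 0.5 added. ACAT2, an acetyl-CoA acetyltransferase, fell by −2.08 ± 0.45 (edgeR adjusted p = 0.00957), and by −1.37 without control replicate 1. IDI1, isopentenyl diphosphate isomerase, fell by −1.38 ± 0.37 (edgeR adjusted p = 0.0205) and by −0.79 without control replicate 1, and did not pass without any of MK5 siRNA replicates 1 (edgeR adjusted p = 0.0642), 2 (0.0685) or 3 (0.0749). Of 29 hypoxia and glycolysis genes, 10 fell and 5 rose, also when adjusted over the list alone. PKM, pyruvate kinase, fell from 4018 ± 331 to 1250.1 ± 230.1 CPM (−1.68 ± 0.16) and the glucose transporter gene SLC2A3 rose by 2.56 ± 0.40 (edgeR adjusted p = 0.000530 and 0.00253). The median was −0.52 (camera adjusted p = 0.246).

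Survival and growth arrest genes went both ways. Of 26 p53 target genes, 7 fell and 3 rose, with 6 and 2 when adjusted over the list alone. ZMAT3, an RNA-binding protein gene, fell from 187 ± 13.7 to 32.5 ± 3.85 CPM (−2.52 ± 0.13), and the kinase gene PLK2 by −1.18 ± 0.22 (edgeR adjusted p = 0.000178 and 0.00493). The median was −0.28 (camera adjusted p = 0.135). The list passed without control replicate 1 (camera adjusted p = 0.0343) and without replicate 1 in both groups, with a median of −0.43 (camera adjusted p = 0.00721). Of 17 FOXO target genes, 8 rose and 2 fell, also when adjusted over the list alone, with a median of 0.43 (camera adjusted p = 0.131). KLHL24 rose by 2.39 ± 0.20 (edgeR adjusted p = 0.000353). FBXO32, the ubiquitin ligase atrogin-1, rose by 1.57 ± 0.54 (edgeR adjusted p = 0.0484) and did not pass with the replicate number as a block (edgeR adjusted p = 0.0942), or without control replicate 3 (edgeR adjusted p = 0.0696) or MK5 siRNA replicate 1 (0.148), 2 (0.0819) or 3 (0.0866). Nor did it pass with a mean of at least 5 CPM (edgeR adjusted p = 0.0519), with no abundance trend (0.0501) or in the robust fit (0.0510). Of 23 genes of the BCL2 family and apoptosis, 8 rose and 4 fell, also when adjusted over the list alone. HRK, a cell death activator, rose by 2.99 ± 0.25 to 4.66 ± 0.90 CPM and BCL2L2, a survival factor, by 1.06 ± 0.19 (edgeR adjusted p = 0.000342 and 0.00417), with a list median of 0.07 (camera adjusted p = 0.634).

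Matrix and TGF-beta genes showed no common direction that passed. Of 32 extracellular matrix genes measured, 9 rose and 5 fell, also when adjusted over the list alone, with a median of 0.16 (camera adjusted p = 0.645). COL1A1, a collagen chain, rose by 1.83 ± 0.35 and the proteoglycan gene BGN fell by −1.75 ± 0.28 (edgeR adjusted p = 0.00605 and 0.00291). Of 20 TGF-beta response genes, 6 rose and 1 fell, with 5 and 1 when adjusted over the list alone. PMEPA1, a feedback inhibitor of TGF-beta signalling, rose from 14.0 ± 1.59 to 94.4 ± 19.3 CPM (2.75 ± 0.18) and the AP-1 gene JUNB by 1.78 ± 0.26 (edgeR adjusted p = 0.000209 and 0.00209). The median was 0.27 (camera adjusted p = 0.0994), and the list passed without MK5 siRNA replicate 2 (camera adjusted p = 0.0351) or replicate 3 (0.0245).

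Markers of cell types were measured at low levels for the most part. Of 7 measured retinal pigment epithelium markers, PMEL and MITF fell by −1.89 ± 0.27 and −1.09 ± 0.14 (edgeR adjusted p = 0.00189 and 0.00114), none rose and the median was −0.53 (camera adjusted p = 0.246). Of 7 epithelial and keratinocyte markers, 3 fell and 1 rose, with CLDN4 at −2.18 ± 0.48 and KRT8 at −0.83 ± 0.18 (edgeR adjusted p = 0.00990 and 0.0104) and a list median of −0.54 (camera adjusted p = 0.532). Of 15 mesenchymal and fibroblast markers, 3 fell and 2 rose, including S100A4 at −2.60 ± 0.52 (edgeR adjusted p = 0.00656), beside SNAI1, with a median of −0.15 (camera adjusted p = 0.634). Of 7 endothelial markers, 4 fell and 1 rose, and the median was −2.12 (camera adjusted p = 0.0552). The receptor gene TIE1 fell from 22.3 ± 8.32 to 3.35 ± 0.475 CPM (−2.73 ± 0.33, edgeR adjusted p = 0.00101). VWF fell by −2.95 ± 0.85 (edgeR adjusted p = 0.0269), by −1.77 without control replicate 1, and did not pass without MK5 siRNA replicate 1 (edgeR adjusted p = 0.0922), 2 (0.0511) or 3 (0.0911). Nor did it pass in limma with a pseudocount of 0.5 (−1.23, limma adjusted p = 0.0569) or 2 (−0.54, 0.101) or after quantile normalization (−1.34, 0.0557). The endothelial list passed with the replicate number as a block (camera adjusted p = 0.0260), and without control replicate 2 (0.0359) or 3 (0.0421) or any of MK5 siRNA replicates 1 (0.0444), 2 (0.0300) and 3 (0.0392). It also passed with scaling by library totals alone (camera adjusted p = 0.0450), without replicate 1 in both groups (0.0343) and without genes with a 7-base site (0.0358). All 3 measured haematopoietic markers fell, from a summed 10.9 to 0.912 CPM, with LAPTM5 at −4.70 ± 0.83 and CD34 at −4.24 ± 0.44 (edgeR adjusted p = 0.00418 and 0.000648). Of 5 neuronal markers, SNAP25 rose by 2.45 ± 0.29 and MAP2 fell by −0.59 ± 0.14 (edgeR adjusted p = 0.000938 and 0.0117), with a median of 0.09 (camera adjusted p = 0.634), and MAP2 did not pass without MK5 siRNA replicate 2 (edgeR adjusted p = 0.0550) or 3 (0.0582). When adjusted over each list alone, the counts were the same in these 6 lists except that 5 endothelial markers fell.

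Of 13 genes of the microRNA and siRNA machinery, 4 fell and 1 rose, also when adjusted over the list alone. The median was −0.06 and the list did not pass (camera adjusted p = 0.867). TNRC6C and TNRC6A, which encode scaffold proteins of silencing complexes, changed by 1.18 ± 0.29 and −0.92 ± 0.29 (edgeR adjusted p = 0.0155 and 0.0369). TNRC6C did not pass without control replicate 2 (edgeR adjusted p = 0.0532), control replicate 3 (0.0539) or MK5 siRNA replicate 1 (0.0559). TNRC6A changed by −0.52 without control replicate 1 and did not pass without MK5 siRNA replicate 1 (edgeR adjusted p = 0.0616), 2 (0.116) or 3 (0.121).

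**Figure D3:**
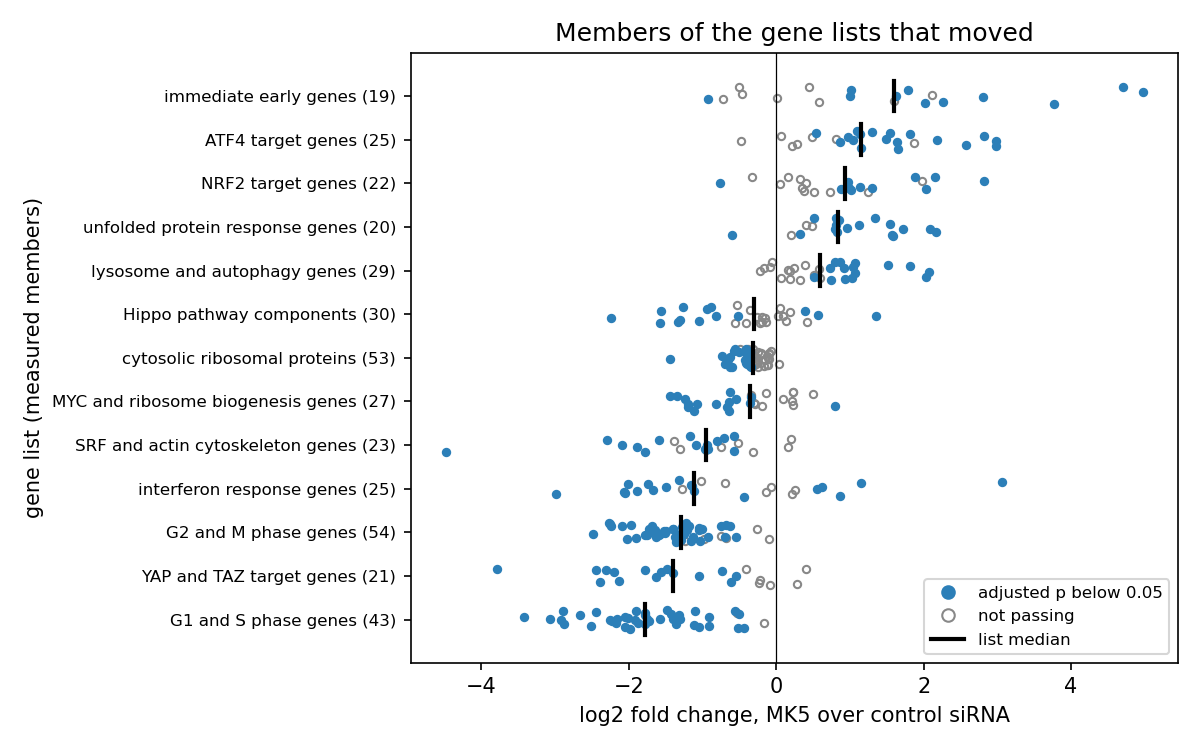
Log2 fold change of MK5 over control siRNA for each measured member of the 13 lists that passed camera, with filled points for genes that passed edgeR's test and a bar at each list's median. The medians run from −1.78 in G1 and S phase genes to 1.60 in immediate early genes.

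In all, 13 of 33 lists passed camera, 5 upward and 8 downward, each with a median of the same sign in replicate pair 1 as in the mean of pairs 2 and 3, on CPM with 0.5 added. In that order, the medians were −1.11 and −1.09 for YAP and TAZ targets, −0.345 and −0.21 for Hippo components, −0.53 and −1.03 for actin cytoskeleton genes, −2.28 and −1.47 for G1 and S phase, and −1.88 and −0.90 for G2 and M phase. They were −0.58 and −0.86 for interferon response genes, −0.54 and −0.40 for ribosome biogenesis and −0.38 and −0.30 for ribosomal proteins. Upward, they were 1.66 and 0.67 for immediate early genes, 0.85 and 0.86 for the unfolded protein response, 0.90 and 1.58 for ATF4 targets, 1.11 and 0.51 for NRF2 targets and 0.78 and 0.47 for lysosome and autophagy genes. These 13 lists were picked by camera on the same libraries, so their shared signs were largely set in advance and are no separate support. Among the lists that did not pass, and with no test of the pairs, the sign of the median differed between pair 1 and pairs 2 and 3 for ERK feedback genes (−0.60 and 0.40), p53 targets (0.17 and −0.43), the BCL2 family (0.27 and −0.06), the microRNA and siRNA machinery (−0.27 and 0.08) and neuronal markers (0.52 and −0.06). Medians were more than 2 times as far from 0 in pair 1 for hypoxia and glycolysis genes (−0.92 and −0.13), TGF-beta response genes (0.86 and 0.14), NF-kB genes (1.14 and 0.26), extracellular matrix genes (0.46 and 0.09), mitochondrially encoded genes (0.30 and 0.07) and histone genes (1.21 and 0.40). With an estimated correlation between members, camera called 0 of the 33, with 5 at an unadjusted p below 0.05. That setting has little power with 6 libraries, so it does not decide whether the lists moved. In fry, which tests whether members move one way on balance, 16 passed.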

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

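Scaling by library totals alone, a mean of at least 1 CPM, limma with a pseudocount of 0.5, leaving out replicate 1 in both groups, and leaving out genes with a 7-base site in the 3′ UTR were chosen after the data were seen. MAPKAPK5 fell in each setting that tested it, with log2 fold changes from −1.09 to −0.90 and edgeR adjusted p of at most 0.0125 in the edgeR settings. It has no value without genes that hold a site, since its own 3′ UTR holds the word. The number of changed genes stayed within 1.5 times of 6206 in all settings except without replicate 1 in both groups, where it was 10372, with 5195 higher and 5177 lower. In that setting the spread rested on 2 libraries per group that differed little and might not be separate cultures. With single libraries left out, it ranged from 4167 without MK5 siRNA replicate 2 to 8874 without control replicate 1, and the genes that fell ranged from 2103 to 4419. No gene called in both the main test and an alternative changed direction in any setting. Scaling by library totals alone moved the median of all tested genes by 0.10 on the log2 scale and gave 3544 higher and 2714 lower genes. DESeq2 called 6832 genes and gave no adjusted p for FOS and NPPB.

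Lists depended more on the test than genes did. Camera called 13 lists, 21 with no filter on low counts and 0 with an estimated correlation between members. The cause of the rise with no filter was not tested. With no filter, cholesterol synthesis genes (camera adjusted p = 0.0240), p53 targets (0.0435), FOXO targets (0.0442) and TGF-beta response genes (0.0381) were among the lists that newly passed. Integrins (camera adjusted p = 0.0259), NF-kB genes (0.0439) and endothelial markers (0.0127) did so as well. The count of 21 also takes in the haematopoietic list, which had 3 measured members with the filter and was not tested there. Among the 13 lists the estimated correlations ran from 0.000217 for lysosome and autophagy genes to 0.821 for G2 and M phase genes, so values above the preset 0.01 cannot explain every loss. In that setting camera also refers its statistic to the residual degrees of freedom of the 6 libraries, which leaves it little power. The 0 calls therefore do not show that these lists fail, and the 13 calls do not allow for correlations above 0.01. How much of the loss came from each was not tested. In fry, the immediate early list (adjusted p = 0.0910) and the ribosomal proteins (adjusted p = 0.0604) no longer passed, while FOXO targets (0.0286), integrins (0.00506) and the retinal pigment epithelium (0.00472), epithelial (0.0249) and endothelial (0.000398) lists did. The Hippo list did not pass once genes with a site, 11 of its 30 members, were left out (camera adjusted p = 0.122). Among lists that did not pass, 6 turned direction in camera in some setting, which need not show in the median, and the cause was not tested. The p38 and MK kinase module gave a median of −0.16 with no filter, 0.21 without replicate 1 in both groups, −0.0724 without genes with a site, and from −0.0803 to 0.16 with single libraries left out. Without replicate 1 in both groups the extracellular matrix list gave 0.0916 and the microRNA and siRNA machinery 0.0764, and the BCL2 family gave −0.10 without genes with a site. With single libraries left out, medians ranged from −0.22 to 0.45 for ERK feedback genes, from −0.0535 to 0.23 for mitochondrially encoded genes and from −0.16 to 0.0645 for the microRNA and siRNA machinery. LATS1 ranged from −0.00990 to 0.31 and LATS2 from −0.0919 to 0.21. Of the 111 named genes that passed besides MAPKAPK5, 12 lost their call in at least 1 setting and none changed direction while called.

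With the replicate number as a block, 6359 genes changed, 5747 of them shared with the unblocked 6206, and 15 lists passed. The block ended the call of FBXO32 and brought in the cholesterol synthesis and endothelial lists, and the p38 and MK kinase module, at a median of −0.0771, turned direction in camera. It changed no other call among the named genes and lists. Low counts limit 12 named genes with 7 to 17 counts in their lower group: LAPTM5, CD34, EGR2, CXCL2, ITGB2, HIST2H2AC, CNN1, VWF, IFI27, NR4A3, NPPB and S100A4. In simulated counts with few changed genes, where the adjusted threshold is stricter than here, the edgeR test recovered 0% of 67 genes changed 1.5-fold.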

Other observations

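The test of 3′ UTR length and base composition, the test of replicate 1 for the number of changed genes and the test of sequencing depth were chosen after the results were seen. The sequence words were found by a search over all words of 7 bases, and the genes named with their words were chosen after their values were seen. Control replicate 1 differed from control replicates 2 and 3 in recognisable gene groups, given here as median log2 differences with no test, since 1 library stands against 2. Cholesterol synthesis genes were higher in it by 1.08, ERK feedback genes by 0.91, G2 and M phase genes by 0.86, hypoxia and glycolysis genes by 0.81 (0.805), the microRNA and siRNA machinery by 0.78 and ATF4 target genes by 0.68. Replication-dependent histone genes were lower at −1.78, the 3 haematopoietic markers at −0.84, neuronal markers at −0.74, extracellular matrix genes at −0.61 and mitochondrially encoded genes at −0.54. MK5 siRNA replicate 1 shared part of this, with haematopoietic markers at −0.63 and mitochondrially encoded genes at −0.29. It was higher than MK5 siRNA replicates 2 and 3 in immediate early genes by 0.87, NF-kB and inflammatory genes by 0.54 and TGF-beta response genes by 0.48, and lower in G1 and S phase genes at −0.47. Cholesterol synthesis genes differed there by 0.15 and G2 and M phase genes by −0.12.

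Genes holding the 7-base word TCCAGTT in the 3′ UTR were lower with MK5 siRNA: among 16350 words scored in 12299 genes it had the lowest z value, −10.4 over 2043 genes, where 100 shuffles reached −4.94, and the median log2 fold change was −0.38 in 455 genes with TCCAGTTA, −0.19 in 1588 with TCCAGTT alone and 0.07 in 7554 with no site. The values argue against 3′ UTR length or base composition, since the lowest z among other words of the same bases that shared no 6 bases with it was −3.47, within the range of the shuffles, and against replicate 1 as the source, since the weaker coefficient of replicate pairs 2 and 3 was −0.26 with a standard error of 0.02 across genes, which are not independent replicates. A candidate explanation is pairing of the MK5 siRNA's seed with other transcripts, as the coefficient was −0.29 in the 3′ UTR and −0.21 in the coding part, a difference of −0.0807 ± 0.0372 (SE). This difference was −0.07 ± 0.04, −0.09 ± 0.03 and −0.08 ± 0.03 in pairs 1, 2 and 3, and the fall with the word was not confined to the 3′ UTR. Both coefficients were fitted together, so their difference does not divide the fall in the 3′ UTR into specific and unspecific shares. Words in coding parts were not set against shuffles. Loss of MK5 acting through its own pathway cannot be told apart from it, because the series holds 1 MK5 siRNA group and the siRNA sequence is not given in the sources used here, though the coding part of MAPKAPK5 holds TCCAGTTA once, as do 2.03% of 2955 coding parts of like length. If seed pairing acts, it may reach YAP1, whose 3′ UTR holds 3 sites of 7 or 8 bases, a number found in 1.46% of genes. It may also reach AMOTL2 (1 site), PTK2 (1 of 8 bases, log2 fold change −2.27) and ZMAT3 (6 sites, −2.52). CYR61, CTGF, ANKRD1 and AXL hold none in the 3′ UTR, but the coding parts of ANKRD1 and CRIM1 hold TCCAGTT once and that of YAP1 holds CCAGTTA once. An indirect fall of such genes through YAP1 was not tested. LATS1 holds TCCAGTTA at a log2 fold change of 0.14. The excess of falls over genes with no site was 315 of 3022 falls (10.4%). That count is not corrected for length, base composition or level and leaves out sites in coding parts, so it does not measure the reach of seed pairing.

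For the change in 46.2% of the tested genes, the 10 splits of the 6 libraries into 3 and 3 are too few for a share under 0.05, with 6206 genes in the real split, the 1 split that gave as many, and 0 by edgeR in the highest other, where at most 515 genes had an unadjusted p below 0.05, limma called 0 and DESeq2 at most 7. Of the 4 splits that part all 3 replicate pairs, the 3 others also gave 0 by edgeR, with at most 365 genes at an unadjusted p below 0.05, 0 by limma and at most 7 by DESeq2. Every other split puts libraries of both siRNAs on each side, so the difference between the groups enters its spread. Low counts in those splits were thus largely set in advance and decide nothing here. The values argue against the choice among the scalings tried as the source of the 6206 changed genes, with 6258 when scaled by totals alone. The directions did shift, to 3544 higher and 2714 lower genes. All these scalings are relative, so a change in the total RNA of the cells could not be seen. Replicate 1 stays open as a contributor, since 19.8% and 20.4% of all tested genes differed at least 2-fold in pairs 2 and 3 against 25.9% in pair 1, the lower being 76.7% of pair 1, and the calls without it cover most tested genes and decide little. A broad response to MK5 loss, off-target silencing and a shared effect of the MK5 siRNA on growth or stress all remain open, and no second siRNA or rescue group was analysed here.

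Replicate 1 stood apart from replicates 2 and 3 in both groups, and most in the controls, where it lay farthest out on the second principal component. Sequencing depth is argued against, since totals of replicate 1 differed from the others of its group by at most 2.49%. GC content and transcript length took up at most 3.69% of the variance of its deviation, in the controls, and 0.965% in the MK5 siRNA libraries, which argues against them as the main source. A separate day of culture, cell density or library preparation stays open and untested, since the labels name none, and the design gives no biological factor that parts replicate 1, so no biological explanation was tested.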
